A study of Mus musculus with 4 samples.

How the data were processed

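RNA was measured on 4 Affymetrix mouse arrays, 1 per sample. Of these, 2 held RNA of flow-sorted Lgr5(hi) intestinal stem cells from wild-type mice, and 2 held RNA of villus cells taken off with EDTA from mice with a conditional Atoh1 knockout in the intestinal epithelium, called enterocytes by the submitters. Per the labels' protocols, total RNA of proximal intestinal epithelium from C57BL/6 mice aged 4 to 6 weeks was extracted with Trizol and a column kit, and biotinylated cRNA was made from 100 ng. Tamoxifen at 1 mg per day over 5 days with a wait of 5 days is given in the labels of all 4 samples, the wild-type stem samples included. The samples of a group are labelled biological replicates, but the animals behind them are not named.

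Values were deposited as normalized intensity per probe set on a linear scale, from 7.93 to 41703.8, with array medians of 110.6 and 109.5 in the stem arrays and 102.4 and 103.8 in the enterocyte arrays. RMA is the processing tool named, per the submitters' processing notes, with no version. Since RMA gives log2 values, the deposited intensities appear to have been taken out of the log; how the arrays were normalized against each other, and whether other arrays took part, is not given in the sources used here. The planned design assumed log2 values and provided for this case: log2 of each deposited intensity was taken, with no pseudocount, and nothing else was done to the values. No column was without a sample (0 columns).

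Of 22690 probe sets, 64 were control probe sets. The platform annotation listed 21084 probe sets, gave exactly 1 gene symbol for 20380 and several for 691, and did not list 1606. Entrez identifiers of 20351 probe sets matched the RefSeq gene table of assembly GRCm38.p6, which was used for names only, 29 did not match and kept the name of the annotation, and 0 symbols needed updating. For each of 12393 genes, the probe set with the highest mean over the 4 arrays was used; 4956 genes had several probe sets. Where several probe sets of a gene passed the threshold, they pointed in opposite directions in 89 of 1464 genes (6.08%), none of them among the genes chosen by the rule given below.

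Group differences (enterocyte minus stem, log2) were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all 12393 genes and a threshold of 0.05 on the adjusted p. The fit had 2 residual degrees of freedom and 1.23 prior degrees of freedom. In 209 genes both replicates of both groups had identical deposited values, which limma handles by an offset. Counted per group, the replicates were identical in 1268 genes of the stem group and 1048 of the enterocyte group. Such ties lower the spread seen between replicates. Gene lists were tested with camera of limma at its preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 29 lists, and again with the correlation estimated from the data and with fry. With an estimated correlation, camera tests on the 2 residual degrees of freedom, so few lists can pass with this few arrays. Errors given as SE are limma's standard errors of the log2 difference with n = 2 arrays per group, except where said to be across genes. The number of arrays limits the precision.

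A background level was set at the 90th percentile of the mean level of 26 genes of other organs, such as eye, testis and heart: log2 5.64, an intensity of 49.9. Adjusted p passed the threshold for 0 of these 26 genes by limma. Where 1 group lay below that level and the other above it, the fold is written as "at least", the brighter group's mean over the mean of the other group with each array raised to at least the background level.

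Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Atoh1 and Lgr5, the 6 genes with the largest increase and the 6 with the largest decrease past the threshold, and in each list up to 3 members with the largest difference past the threshold in the list's main direction and 1 in the other direction; Alpi, Fabp1, Olfm4, Ascl2, Mki67, Muc2, Lyz1, Chga, Dclk1 and Hes1 are given whatever their p. It gave 95 genes, of which those most telling for each list are printed. Alpi, Olfm4 and Muc2 had no probe set of their own under these annotations and were not analysed here. Genes named beyond the rule are said to be so.

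The steps were tested on simulated data with known changes in 12393 genes. With 50 genes changed at each size, limma recovered 0% of those changed by 0.5 (log2), 26% at 1, 74% at 2 and 90% at 4, with 2 false calls. With 40% of genes changed, it recovered 62.9%, 85.7%, 96.8% and 99.6% at the same sizes, and 3.45% of 4433 calls were false. Noise was simulated independently for each gene, with no processing difference between the groups, and only brighter genes were changed in the first simulation. The false share therefore does not carry over to the real calls. Alternatives covered the replicate block, the treatment of several probe sets per gene, probe sets that may cross-hybridise, dim genes, scaling between arrays, the variance model, array weights, a test against a 1.5-fold difference, and leaving out each array in turn. Principal components and correlations across genes described the replicates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.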

Results

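Gene expression was measured in the stem cells and in the absorptive cells of the mouse small intestine. Lgr5(hi) stem cells, which sit at the crypt base and renew the epithelium, were sorted by flow cytometry from wild-type mice (2 arrays). Villus cells were released with EDTA after deletion of Atoh1, the transcription factor that secretory cells need, so that the villus fraction would consist of enterocytes (2 arrays). The comparison addresses how expression differs between intestinal stem cells and differentiated enterocytes. Cell type, genotype and isolation change together between the groups, so each difference below is a difference in all of them at once. Signals of control probe sets also differed between the groups, as given further on. Differences in array processing can therefore not be told apart from these either, and how far they moved the gene differences was not tested. Array medians lay between 102.4 and 110.6 intensity units, and 12393 genes were tested.

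Enterocyte and stem cell arrays differed widely. At the threshold, 2257 genes were higher and 2779 lower in the enterocyte arrays (limma), 40.6% of the genes tested, and of these 1344 were higher and 1689 lower by at least 2-fold. On the deposited values 118 genes rose and 23 fell by at least 16-fold. With dim values raised to the background level, a count added after the data were seen, 103 rose and 15 fell by at least 16-fold, and 1285 and 1640 by at least 2-fold. Among the lists called by camera, digestive hydrolases, xenobiotic metabolism, nutrient transporters and lipid absorption had the highest medians, and goblet cell markers, stem cell markers, ribosome biogenesis and Wnt targets the lowest. Across genes, which are not independent replicates, replicates correlated at r = 0.996 in the stem group and 0.992 in the enterocyte group, against 0.890 to 0.898 between groups. The first principal component held 94.3% of the variance. By camera 11 of 29 lists were higher and 10 lower, and with an estimated correlation 0 lists passed, the smallest adjusted p being 0.229. That setting tests on 2 residual degrees of freedom. Digestive hydrolases and Wnt targets had estimates of -0.0204 and -0.0426, below the preset 0.01, and still went to 0.229. Other lists had higher estimates, up to 0.419 for lymphocyte markers. The lost calls therefore need not reflect correlation between genes. The test fry called 26 lists. Leaving out either stem array ended every call by limma (0 genes, with 4675 and 4817 at an unadjusted p under 0.05). Without enterocyte replicate 1 663 genes remained past the threshold as higher and 1058 as lower, and without enterocyte replicate 2 these were 570 and 853. Centring each array on the median level of 11 reference genes moved the median difference of all genes from -0.00261 to -0.78. The split became 1173 higher and 9567 lower, and every list median below is lowered by 0.778. That shift compares different genes, as the middle reference gene was Pgk1 in the stem and Ywhaz in the enterocyte arrays. Of the 11 reference genes 2 were higher and 4 lower past the threshold by limma. Neither this centring nor the next therefore rests on stable genes alone. Centring on reference gene differences, chosen after the data were seen, raised every list median instead. It gave fatty acid oxidation 1.195 (13 rises, 0 falls), enterocyte transcription factors 0.988 (14 rises, 3 falls) and tuft cell markers 1.115 (10 rises, 0 falls).

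**Figure D1:**
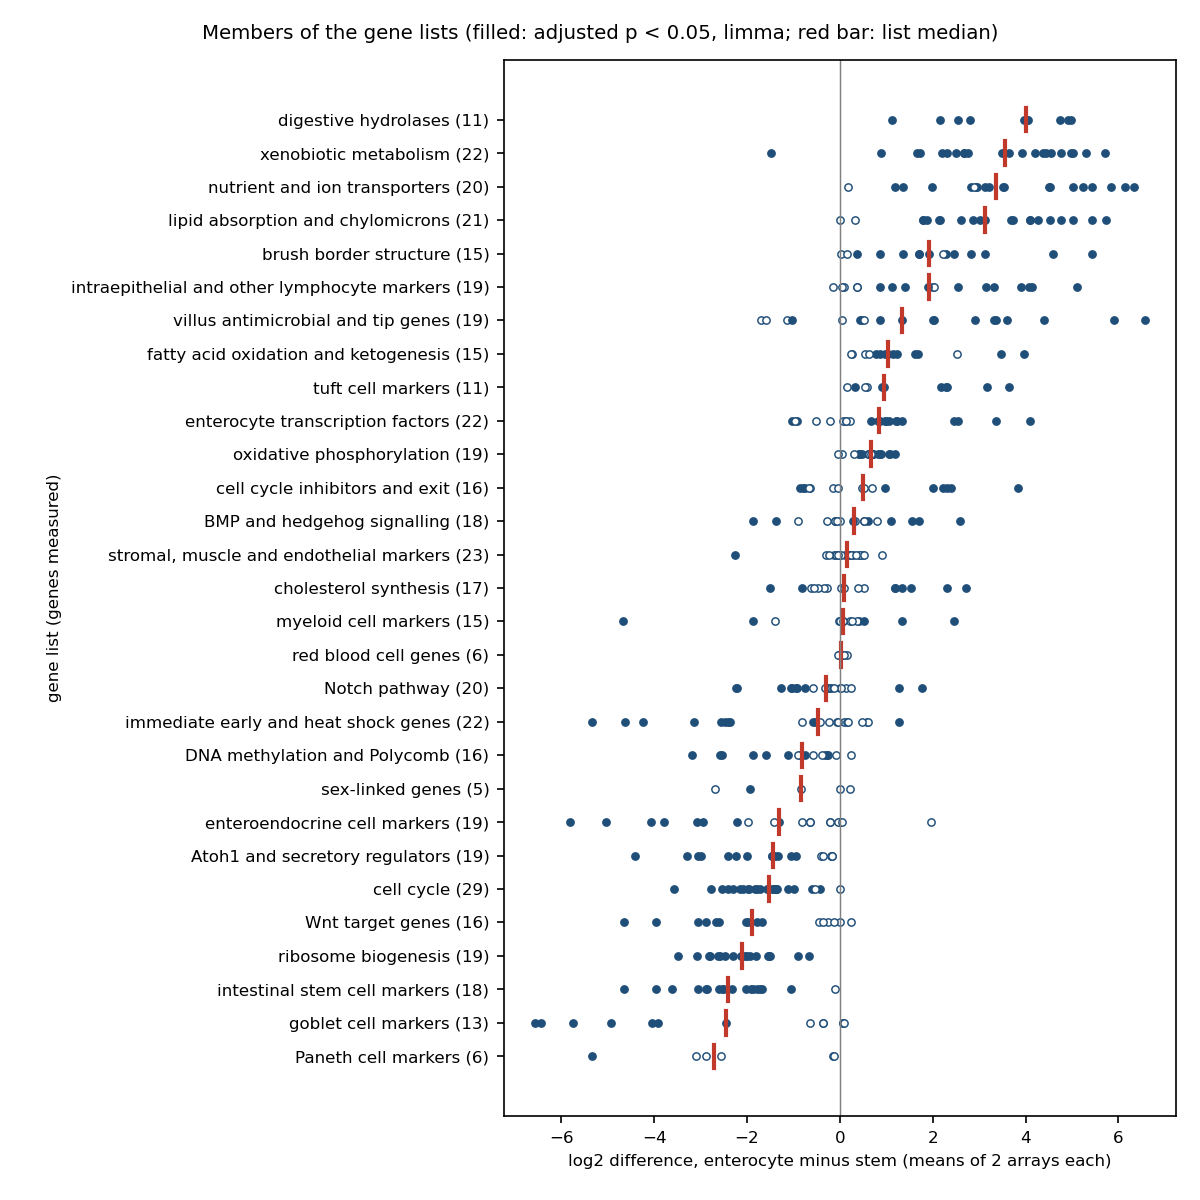
Log2 difference (enterocyte minus stem, x axis) of every measured member of the 29 gene lists (y axis, with the number of genes measured); filled points passed the limma threshold, open points did not, and red bars are list medians. Digestive hydrolases have a median of 4.01, stem cell markers of -2.41 and red blood cell genes of 0.03.

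The targeted gene Atoh1 was low in both enterocyte arrays, at log2 5.06 and 5.28, below the background level of 5.64, and was 7.43 and 7.71 in the stem arrays. It was at least 3.81-fold lower (log2 difference -2.40 ± 0.15 SE, n = 2 arrays per group, adjusted p = 0.00423 by limma). Which part of the gene was deleted is not given in the sources used here, so this probe set need not lie within it. Lgr5, the receptor used for the sort, was 24.9-fold lower in enterocytes (-4.64 ± 0.36 SE, adjusted p = 0.00584). Both directions were set by the design.

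Stem cell markers fell as a group. Of 18 measured markers 17 fell, 0 rose and 1 did not pass the test, and 17 fell when adjusted over the list alone; the list was chosen for known stem cell genes and includes the sort gene. The median log2 difference was -2.41, with a camera adjusted p of 7.48e-08 and adjusted p = 0.239 with an estimated correlation. Ascl2, a transcription factor of the stem cell state, fell 8.34-fold (-3.06 ± 0.28 SE). On their brightest probe sets, Tnfrsf19 was at least 7.11-fold lower and Msi1, an RNA-binding protein, at least 6.08-fold lower; their dimmest probe sets, tried after the data were seen, gave -0.09 and 0.21, not past the threshold. Targets of Wnt signalling, the pathway that maintains crypt stem cells, showed 10 falls, 0 rises and 6 members not past the test. Adjusted over the list alone 10 fell, and the median was -1.88 (camera adjusted p = 0.000158, adjusted p = 0.229 with an estimated correlation). Under reference gene centring 16 fell, at a median of -2.66. The Wnt list shares members with the stem cell list, among them the sort gene Lgr5, Tnfrsf19 and Ascl2. Its fall is therefore not independent of that list or of the sort. In the Notch pathway, which holds crypt cells undifferentiated, 8 of 20 members fell, 2 rose and 10 did not pass; adjusted over the list alone 9 fell and 2 rose. Its median was -0.30, its camera adjusted p of 0.0436 became adjusted p = 0.302 with an estimated correlation, and the call was also lost without stem replicate 1 (0.0574, median -0.40), without stem replicate 2 (0.138, median -0.21), without genes below background (0.106, median -0.57) and in further settings. Among these, reference gene centring gave 18 falls and 2 rises, at a median of -1.08 (camera adjusted p = 0.291). The receptor Notch1 fell 4.63-fold (-2.21 ± 0.15 SE) and the Notch target Hes1 2.42-fold (-1.27 ± 0.18 SE), while Numb, an inhibitor of Notch signalling, rose 3.39-fold (1.76 ± 0.15 SE).

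Genes of proliferation were lower in enterocytes. In the cell cycle list 26 of 29 members fell, 0 rose and 3 did not pass (27 falls adjusted over the list alone), with a median of -1.53 (camera adjusted p = 2.60e-09; adjusted p = 0.239 with an estimated correlation). The proliferation marker Mki67 fell 11.9-fold (-3.58 ± 0.29 SE) and Mcm7, a subunit of the replicative helicase, 5.77-fold (-2.53 ± 0.13 SE). Every measured ribosome biogenesis gene fell, 19 of 19 over all genes and over the list alone, with a median of -2.10 (camera adjusted p = 5.59e-08; adjusted p = 0.229 with an estimated correlation). The nucleolar proteins Nop56 and Ncl fell 11.1-fold (-3.48 ± 0.17 SE) and 7.04-fold (-2.81 ± 0.24 SE). Regulators of DNA methylation and Polycomb fell in 10 of 16 cases, with 0 rises and 6 not past the test (12 falls adjusted over the list alone), and a median of -0.81 (camera adjusted p = 0.000434; adjusted p = 0.229 with an estimated correlation). With the mean or the median over probe sets 7 fell, at medians of -0.38 and -0.33, and under reference gene centring 16 fell, at -1.59. Among them Dnmt1, the maintenance DNA methyltransferase, fell 5.96-fold (-2.58 ± 0.12 SE) and the helicase Hells 9.03-fold (-3.17 ± 0.37 SE). Inhibitors of the cell cycle went both ways: 6 of 16 rose, 3 fell and 7 did not pass, the same numbers as when adjusted over the list alone, and camera made no call (median 0.49, adjusted p = 0.147). With reference gene centring 5 rose and 7 fell, at a median of -0.29. Cdkn2b, an inhibitor of cyclin D kinases, rose 14.3-fold (3.84 ± 0.16 SE), and Mxi1 and Mxd1, antagonists of Myc, rose 5.23-fold (2.39 ± 0.11 SE) and 4.98-fold (2.31 ± 0.15 SE). Gadd45b fell by 0.85 on the log2 scale (SE 0.19, adjusted p = 0.0458 by limma), a call lost with the replicate block (adjusted p = 0.0844) or with array weights (0.0511).

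Genes of digestion and nutrient uptake were higher in enterocytes. All 11 measured digestive hydrolases rose, over all genes and over the list alone, with a median of 4.01, a camera adjusted p of 7.48e-08 and adjusted p = 0.229 with an estimated correlation. Trehalase, encoded by Treh, was at least 25.4-fold higher (4.97 ± 0.06 SE), and angiotensin-converting enzyme, Ace, was 30.1-fold higher (4.91 ± 0.10 SE). Mep1b, a meprin metalloprotease, was 26.6-fold higher (4.73 ± 0.10 SE). Of 20 nutrient and ion transporters 18 rose, 0 fell and 2 did not pass (19 rises adjusted over the list alone). Their median was 3.37 (camera adjusted p = 5.31e-10, adjusted p = 0.229 with an estimated correlation). The glucose transporter gene Slc2a2 rose 81.0-fold (6.34 ± 0.23 SE). The iron exporter gene Slc40a1 rose 57.5-fold (5.85 ± 0.41 SE) and the peptide transporter gene Slc15a1 at least 30.6-fold (6.15 ± 0.28 SE). Brush border genes, which build the microvilli, rose in 12 of 15 cases with 0 falls and 3 not past the test (12 rises adjusted over the list alone), with a median of 1.92 that was 1.14, with 10 rises and 3 falls, under reference gene centring (camera adjusted p = 1.02e-06; adjusted p = 0.229 with an estimated correlation). Krt20, a keratin of differentiated cells, rose 43.3-fold (5.44 ± 0.16 SE) and the scaffold gene Pdzk1 24.1-fold (4.59 ± 0.24 SE). The lymphocyte list described further on, with a median of 1.92, moved in the same direction.

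Lipid absorption genes rose in 19 of 21 cases, with 0 falls and 2 not past the test (19 rises adjusted over the list alone), at a median of 3.13 (camera adjusted p = 4.25e-11; adjusted p = 0.229 with an estimated correlation). Rbp2, which binds retinol in the cell, rose 53.4-fold (5.74 ± 0.07 SE). The apolipoprotein gene Apoc2 rose 43.2-fold (5.43 ± 0.32 SE), Mogat2, an enzyme of triglyceride resynthesis, 32.5-fold (5.02 ± 0.10 SE), and the fatty acid binding protein gene Fabp1 6.07-fold (2.60 ± 0.10 SE). In fatty acid oxidation 10 of 15 genes rose, 0 fell and 5 did not pass (13 rises adjusted over the list alone), at a median of 1.04 that was 0.26, with 6 rises and 1 fall, under reference gene centring (camera adjusted p = 3.04e-05; adjusted p = 0.302 with an estimated correlation). Acaa1b and Ehhadh, of peroxisomal oxidation, rose 15.7-fold (3.97 ± 0.35 SE) and 11.0-fold (3.46 ± 0.21 SE). Oxidative phosphorylation genes rose in 13 of 19 cases, with 0 falls and 6 not past the test (17 rises adjusted over the list alone), at a median of 0.66 that turned to -0.11, with 1 rise and 6 falls, under reference gene centring (camera adjusted p = 4.66e-06 as deposited; adjusted p = 0.325 with an estimated correlation). Centring on reference gene differences, chosen after the data were seen, gave 0.82 with 17 rises and 0 falls. Ndufa9, of complex I, rose 2.28-fold (1.19 ± 0.13 SE). Xenobiotic metabolism genes rose in 21 of 22 cases and fell in 1, also when adjusted over the list alone, at a median of 3.57 (camera adjusted p = 1.75e-09; adjusted p = 0.229 with an estimated correlation). The cytochromes P450 Cyp3a13 and Cyp3a11 rose 52.0-fold (5.70 ± 0.05 SE) and 39.6-fold (5.31 ± 0.18 SE), and the carboxylesterase gene Ces1e fell 2.79-fold (-1.48 ± 0.16 SE). Cholesterol synthesis genes were split, with 6 of 17 higher, 2 lower and 9 not past the test (6 higher and 4 lower adjusted over the list alone), and camera made no call (median 0.09, adjusted p = 0.233). Reference gene centring gave 6 rises and 9 falls, at a median of -0.69. Sc5d and Msmo1, late steps of that pathway, rose 6.62-fold (2.73 ± 0.08 SE) and 4.98-fold (2.32 ± 0.24 SE). Sc5d had 0.68 on its dimmest probe set, not past the threshold. The squalene synthase gene Fdft1 was -1.51 ± 0.22 SE, a call lost with the median over its probe sets (-0.17) and without probe sets that may cross-hybridise (-0.36).

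Transcription factors of enterocytes rose in 13 of 22 cases, fell in 2 and did not pass in 7 (13 rises and 5 falls adjusted over the list alone), at a median of 0.83 that was 0.06, with 7 rises and 9 falls, under reference gene centring (camera adjusted p = 0.0019; adjusted p = 0.229 with an estimated correlation). Creb3l3, a regulator of lipid metabolism, rose 17.0-fold (4.09 ± 0.16 SE) and the nuclear receptor gene Nr1i3 5.84-fold (2.54 ± 0.09 SE). Cdx2, a homeobox factor of intestinal identity, fell 2.03-fold (-1.02 ± 0.11 SE), with 0.12 on its dimmest probe set. In BMP and hedgehog signalling 7 of 18 genes rose, 2 fell and 9 did not pass (8 rises and 3 falls adjusted over the list alone), with no call by camera (median 0.30, adjusted p = 0.146). Under reference gene centring 4 rose and 9 fell, at a median of -0.47. The ligand gene Bmp2 rose 6.02-fold (2.59 ± 0.10 SE) and Ihh 2.92-fold (1.54 ± 0.08 SE), and the hedgehog receptor gene Ptch1 fell 3.68-fold (-1.88 ± 0.17 SE), though its dimmest probe set gave -0.21, not past the threshold. Antimicrobial and villus tip genes rose in 12 of 19 cases, fell in 1 and did not pass in 6 (13 rises and 1 fall adjusted over the list alone), at a median of 1.34 that was 0.56, with 10 rises and 3 falls, under reference gene centring (camera adjusted p = 0.000158; adjusted p = 0.325 with an estimated correlation). With the mean or the median over probe sets the median of this list was 2.03. Adenosine deaminase, Ada, rose 95.8-fold (6.58 ± 0.11 SE), the secreted lectin gene Reg1 60.0-fold (5.91 ± 0.08 SE), and the inflammasome gene Nlrp6 fell 2.05-fold (-1.04 ± 0.12 SE).

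Secretory regulators and markers of goblet and enteroendocrine cells were lower in enterocytes, tuft cell markers were higher, and Paneth cell markers gave no call as a list. The enterocyte arrays came from Atoh1 knockouts, and secretory cells need Atoh1. Lower secretory regulators and markers of goblet, enteroendocrine and Paneth cells were thus set in part by the design. They need not show how stem cells and normal enterocytes differ. The regulator list includes Atoh1 itself. Among Atoh1 and other secretory regulators 14 of 19 fell, 0 rose and 5 did not pass (14 falls adjusted over the list alone), at a median of -1.45, or -2.22 with 19 falls under reference gene centring (camera adjusted p = 3.63e-06; adjusted p = 0.239 with an estimated correlation). Neurog3 and Neurod1, factors of the endocrine lineage, were at least 14.6-fold (-4.41 ± 0.18 SE) and at least 6.78-fold (-3.28 ± 0.34 SE) lower. Goblet cell markers fell in 7 of 13 cases, with 0 rises and 6 not past the test (8 falls adjusted over the list alone), at a median of -2.44 (camera adjusted p = 0.00149; adjusted p = 0.325 with an estimated correlation). The median was -1.55 with the mean or the median over probe sets, and 12 of 13 fell under reference gene centring, at -3.22. Zg16, a granule lectin, was at least 88.1-fold lower (-6.57 ± 0.16 SE), and Tff3, a trefoil peptide secreted with mucus, 86.9-fold lower (-6.44 ± 0.07 SE). Enteroendocrine markers fell in 9 of 19 cases, with 0 rises and 10 not past the test (10 falls and 1 rise adjusted over the list alone), at a median of -1.31 (camera adjusted p = 0.00137; adjusted p = 0.325 with an estimated correlation; 0.161 without the dimmer genes, at a median of -3.02). Under reference gene centring 18 fell and 1 rose, at a median of -2.09. Chgb, a granin of endocrine granules, fell 55.9-fold (-5.81 ± 0.42 SE). The hormone gene Gip fell 33.0-fold (-5.05 ± 0.20 SE) and Chga 7.77-fold (-2.96 ± 0.26 SE). Of 6 measured Paneth cell markers 1 fell and 5 did not pass, and 0 passed when adjusted over the list alone (median -2.72, camera adjusted p = 0.152, but 0.0224, at a median of -4.31, without enterocyte replicate 2). Reference gene centring gave 6 falls, at a median of -3.50 (camera adjusted p = 0.605). Lysozyme 1, Lyz1, was at log2 14.75 and 15.12 in the stem arrays and at 8.12 and 11.11 in the enterocyte arrays (-5.33 ± 1.19 SE, adjusted p = 0.0446 by limma), and its call was lost without enterocyte replicate 1 (-3.83) and without probe sets that may cross-hybridise (-0.62). Tuft cell markers rose in 8 of 11 cases, with 0 falls and 3 not past the test (9 rises adjusted over the list alone), at a median of 0.96 that was 0.18, with 5 rises and 2 falls, under reference gene centring (camera adjusted p = 0.000961; adjusted p = 0.325 with an estimated correlation). Alox5ap, of leukotriene synthesis and also present in immune cells, rose 8.93-fold (3.16 ± 0.39 SE), and the tuft cell kinase gene Dclk1 at least 9.37-fold (3.64 ± 0.52 SE), with 0.33 on its dimmest probe set, not past the threshold.

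**Figure D2:**
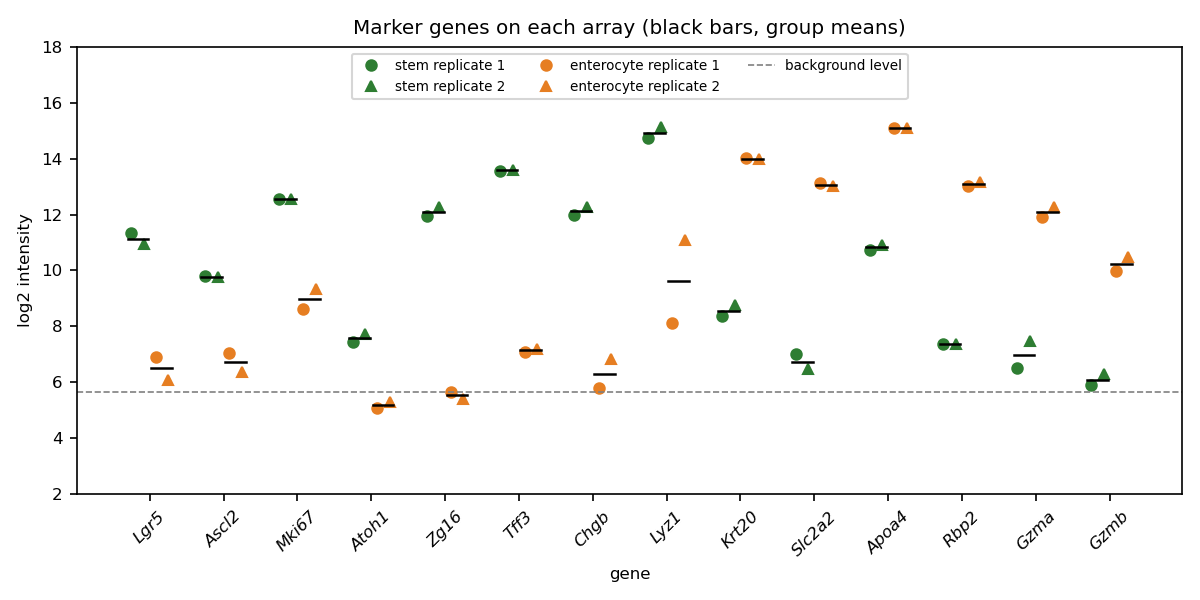
Log2 intensity (y axis) of 14 marker genes (x axis) on each array: green for stem, orange for enterocyte, circles for replicate 1 and triangles for replicate 2, black bars for group means, and a dashed line for the background level of 5.64. Lgr5 is at 11.33 and 10.96 in the stem arrays against 6.92 and 6.09 in the enterocyte arrays, and Lyz1 differs between the enterocyte arrays.

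By log2 difference of the deposited values, the order set by the rule, the genes with the largest changes lay partly outside the lists. The size is uncertain where a group lies below background. By their bounds Cd55 and Pmp22 come after Ada and Slc2a2, Bst1 after Ada, and Egln3 after Slc13a1 and Clec2h. Among the decreases Ccl6 comes after Lyz1 and Gip. Egln3, a prolyl hydroxylase of the oxygen-sensing pathway, was at least 99.3-fold higher in enterocytes (7.74 ± 0.13 SE). The complement regulator gene Cd55 rose at least 65.6-fold (6.78 ± 0.06 SE), Pmp22, a membrane protein best known from myelin, at least 56.7-fold (6.80 ± 0.09 SE), and the surface enzyme gene Bst1 at least 81.2-fold (6.66 ± 0.16 SE). Slc13a1, a sulfate transporter gene, rose 106.8-fold (6.74 ± 0.21 SE) and the lectin-like gene Clec2h 105.0-fold (6.71 ± 0.07 SE). Besides Zg16, Tff3 and Chgb, the rule names among the decreases Spink4, a secreted peptide of goblet cells (53.3-fold, -5.74 ± 0.72 SE, but -4.85 and not past the threshold without enterocyte replicate 1), the chemokine gene Ccl6 (at least 25.8-fold, -5.37 ± 0.30 SE) and the immediate early gene Egr1 (40.4-fold, -5.33 ± 0.16 SE).

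Markers of other cells and of handling also moved with the groups. Lymphocyte markers rose in 13 of 19 cases in the enterocyte arrays, with 0 falls and 6 not past the test (13 rises adjusted over the list alone), at a median of 1.92 that was 1.14, with 12 rises and 4 falls, under reference gene centring (camera adjusted p = 3.70e-06; adjusted p = 0.325 with an estimated correlation). The granzyme genes Gzma and Gzmb rose 34.3-fold (5.10 ± 0.41 SE) and 17.7-fold (4.15 ± 0.26 SE). Ptprc, the pan-leukocyte antigen CD45, rose at least 10.9-fold (4.07 ± 0.36 SE). Of 15 myeloid markers, 8 of them below background in both groups, 3 were higher, 2 lower and 10 not past the test, also over the list alone. The median (0.07) and the mean (-0.15) differed in sign and camera made no call (adjusted p = 0.214). Reference gene centring gave 2 rises and 11 falls, at a median of -0.71. Tyrobp, an adaptor of natural killer and myeloid receptors, was at least 2.14-fold higher (2.46 ± 0.07 SE). Lyz2 was 25.5-fold lower (-4.67 ± 0.80 SE). Its difference was -3.72 without enterocyte replicate 1 and -5.62 without enterocyte replicate 2, neither past the threshold. Such a loss is not particular to Lyz2, Lyz1 and Spink4. Among others, Atoh1, Slc2a2, Cdkn2b and Gzma also lost their calls when either enterocyte array was left out. Lyz2 was at 10.39 and 11.10 in the stem arrays and at 5.12 and 7.03 in the enterocyte arrays. That is the order of the arrays for Lyz1, a Paneth cell marker, so Lyz2 need not mark myeloid cells here. Stromal, muscle and endothelial markers passed in 1 of 23 cases, also over the list alone (median 0.15, camera adjusted p = 0.329): Vim was at least 3.58-fold lower (-2.26 ± 0.23 SE), a call lost without probe sets that may cross-hybridise (difference -1.16, adjusted p = 0.0737 by limma). Of the 23 markers 15 were below background in both groups, and 18 fell under reference gene centring, at a median of -0.62. Red blood cell genes, all 6 below background in both groups and so not informative, passed in 0 cases by limma, over all genes or over the list alone (median 0.03, camera adjusted p = 0.712, with fry's adjusted p 0.186). Their 6 falls under reference gene centring, at a median of -0.75, follow the shift of that scaling. Immediate early and heat shock genes, which respond to handling, fell in 9 of 22 cases, rose in 1 and did not pass in 12 (12 falls and 2 rises adjusted over the list alone), at a median of -0.48 (camera adjusted p = 0.021; adjusted p = 0.503 with an estimated correlation; 0.0627 and a median of -0.44 without stem replicate 2, 0.0823 and -0.34 without enterocyte replicate 2, 0.0629 and -0.54 without genes below background, and 0.107 and -1.26 with 17 falls under reference gene centring). Besides Egr1, Egr2 was at least 9.81-fold lower (-4.62 ± 0.11 SE) and Fosb at least 11.8-fold lower (-4.23 ± 0.20 SE) in enterocytes. Sex-linked genes gave no call as a list (5 measured, median -0.83, camera adjusted p = 0.596), with 1 fall over all genes and over the list alone: Xist was 13.79 and 14.14 in the stem arrays and 12.11 and 11.95 in the enterocyte arrays, a call lost without probe sets that may cross-hybridise (difference -1.90, adjusted p = 0.0691 by limma). Signal from the 3′ end over that from the 5′ end of Gapdh averaged 3.51 ± 0.376 (SD, n = 2) in the stem arrays and 1.12 ± 0.0127 in the enterocyte arrays.

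**Figure D3:**
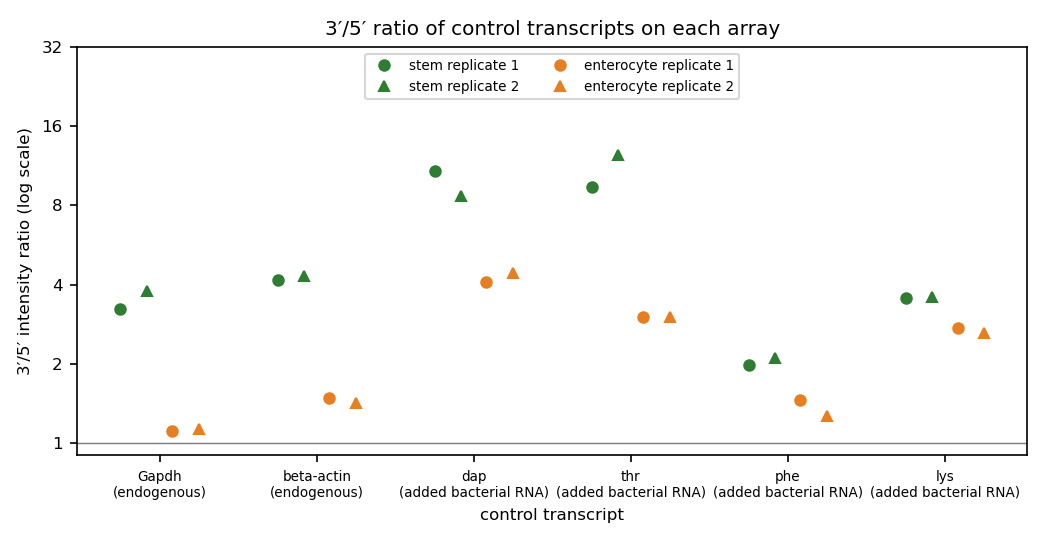
Ratio of 3′ to 5′ intensity (y axis, log scale) of 6 control transcripts (x axis) on each array: green for stem, orange for enterocyte, circles for replicate 1 and triangles for replicate 2. For each transcript both stem arrays lie above both enterocyte arrays; for beta-actin the means are 4.23 and 1.45.

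Spread between replicates was larger in the enterocyte group. The SD of the log2 difference between the replicates was 0.240 in the stem group and 0.315 in the enterocyte group, and 36 and 148 genes differed by at least 2-fold between them; no test was made of this difference. Paneth cell markers had a median difference of 2.92 between enterocyte replicates 2 and 1. Fabp6, an ileal bile acid binding protein named after its value was seen, differed by 4.90.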

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

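Tests of degraded RNA, labelling and dim signals were chosen after the results were seen. Control probe sets, which no comparison used, carried a difference between the groups: the 3′/5′ ratio of Gapdh was 3.51 in the stem arrays against 1.12 in the enterocyte arrays, and the hybridisation control BioB was 4.7-fold brighter in the stem arrays, against 1.65-fold for BioC, 1.52-fold for BioDn and 1.03-fold for CreX, the brightest. Degraded RNA of the sorted cells as the whole cause is argued against by the 4 bacterial RNAs normally added to the sample RNA before labelling, since all 4 showed the same bias and the smallest stem over enterocyte fold was 1.34. Compression of dim signals cannot be judged from BioB, although its 4.7-fold excess in the stem arrays would lower and not raise the ratio there. Added RNAs of like brightness lacked that excess. The 3′ probe set of phe was at 362 and 492 in the stem and at 370 and 287 in the enterocyte arrays. The 5′ probe set of thr went the other way, at 75 and 77 against 232 and 194, but its low stem signal is part of the bias in question. By the values of phe, BioB need not stand for dim signals. Labelling that reached the 5′ end less often in the stem arrays remains a candidate explanation, with a median fold of 1.89 over the 4 added RNAs. Gapdh (3.13-fold) and beta-actin (2.92-fold) lay within the range of the added RNAs, which reached 3.59-fold for thr, and neither a part played by degradation nor a biological explanation was tested.

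Probe sets without a gene in the annotation also carried a signal: of 1555 tested by limma, 382 passed the threshold, 236 of them with at least a 2-fold difference.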

How the results depend on the processing

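Choices made after seeing the data were the dimmest probe set per gene, leaving out genes with identical replicates, and centring on reference gene differences. Leaving out 1 array, with the lone sample assumed to vary like the other group, gave 0 to 663 genes higher and 0 to 1058 lower by limma, and 0 to 526 and 0 to 804 by at least 2-fold; the 0 counts came without stem replicate 1 (smallest adjusted p 0.0524) and without stem replicate 2 (0.0552), and all 5036 genes kept their sign. This test keeps 1 residual degree of freedom. The kept signs carry no information, since a gene past the threshold differs by more than leaving out 1 array can move it. Centring on reference gene levels gave 1173 higher and 9567 lower, and 675 and 4063 by at least 2-fold. The middle reference gene then was Pgk1 in the stem arrays and Ywhaz in the enterocyte arrays, so the shift of -0.78 compares different genes. Centring on the median reference gene difference shifted the median by 0.15 and gave 3091 higher and 2675 lower. Leaving out genes with identical replicates gave 2407 higher and 3000 lower, 1386 and 1763 by at least 2-fold. Testing every probe set gave 3620 higher and 3988 lower, 2265 and 2460 by at least 2-fold, with more units tested. Testing against a 1.5-fold difference gave 1144 higher and 1379 lower, a stricter question. With the replicate block, 2010 genes were higher and 2557 lower; deviations of same-numbered arrays correlated at 0.0504, so the numbers are not taken to pair the arrays, and among named genes the call of Gadd45b alone was lost. Signs turned on the dimmest probe set for Cdx2 (0.12), Fdft1 (0.0739), Msi1 (0.21) and Notch2 (0.15), none past the threshold, and under centring on reference gene levels for Itgax (-0.25); the cause was not tested. Apart from left-out arrays, 86 of 95 named genes kept sign and call in every planned setting that tested them, and 74 with the added ones. Leaving out either stem array ended the call of every named gene. With an estimated correlation 0 lists were higher and 0 lower; leaving the other set tests aside, 23 of 29 lists kept direction and call in every setting that tested them, the exceptions being Notch pathway, immediate early genes, enteroendocrine and Paneth markers, cell cycle inhibitors and cholesterol synthesis. Under centring on reference gene levels the last 2 passed camera upward (adjusted p 0.00245 and 0.0317) with medians of -0.29 and -0.69. Over genes above background, the SD between replicates was 0.242 in the stem and 0.354 in the enterocyte group. Of the 5036 genes, 4847 were above background in at least 1 group.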

Other observations

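The lists added in this paragraph and the next, and the genes named from them, were chosen after the data were seen. Most tRNA synthetase and splicing factor genes were lower in enterocytes. Of 18 tRNA synthetase genes 16 fell, 0 rose and 2 did not pass limma's test (median -0.999, camera adjusted p = 6.15e-06, adjusted p = 0.139 with an estimated correlation). Of 17 splicing factor genes 14 fell, 0 rose and 3 did not pass (median -1.13, camera adjusted p = 2.33e-06, adjusted p = 0.139 with an estimated correlation). Vars fell 5.58-fold (-2.48 ± 0.13 SE, n = 2 arrays per group), Wars 5.32-fold (-2.41 ± 0.17 SE) and Hnrnpdl 4.04-fold (-2.01 ± 0.12 SE). Hypoxia response genes rose in 9 of 18 cases and fell in 1, at a median of 0.87, or 0.09 under reference gene centring (camera adjusted p = 0.00168, adjusted p = 0.437 with an estimated correlation). Without Egln3, whose rise prompted the list, 8 of 17 rose and 1 fell, at a median of 0.82, or 0.04 under reference gene centring (camera adjusted p = 0.00569, adjusted p = 0.452 with an estimated correlation). Pgk1 is both in this list and a reference gene, the middle 1 in the stem arrays. The median of 0.82 is the difference of Pgk1, so the centred 0.04 sets Pgk1 partly against itself. The list has Bnip3 at 14.0-fold (3.81 ± 0.30 SE), Pfkfb3 at least 7.81-fold (3.34 ± 0.30 SE) and Ldha at 5.06-fold (2.34 ± 0.06 SE), whereas Hk2 fell 5.32-fold (-2.41 ± 0.27 SE). Claudins and keratins went both ways, with 6 of 15 higher and 2 lower (median 0.04, camera adjusted p = 0.177): Cldn4 rose 7.07-fold (2.82 ± 0.38 SE) and Cldn2 fell 2.65-fold (-1.40 ± 0.08 SE).

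Interferon response genes did not pass camera (16 measured, 3 higher, 2 lower, median 1.18, adjusted p = 0.0544); Usp18 rose at least 31.9-fold (5.83 ± 0.23 SE), while Ifit1 was at log2 7.39 in enterocyte replicate 1 and 10.05 in replicate 2. MHC class II genes differed by a median of -2.60 between enterocyte replicates 2 and 1 over 6 genes, with H2-Aa at 12.38 in replicate 1 and 8.82 in replicate 2, and gave no call between the groups (1 lower, median -1.65, camera adjusted p = 0.177). Of the sex-linked genes, Eif2s3y, on the Y chromosome, was at 9.05 in stem replicate 1 and at 3.40, 3.43 and 3.63 in the other arrays. Kdm5d, of the same list, was at 5.41 in stem replicate 1 and at 3.90, 3.76 and 3.89 in the others. Xist was at 13.79 in stem replicate 1, so that array held both Xist and a Y-linked transcript. Sex make-up thus differed between the arrays, and whether animals were pooled is not given in the labels.

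Tests of this and the next paragraph were chosen after the results were seen, except that of alpha-defensins. Paneth cell transcripts were higher in enterocyte replicate 2, where Lyz1 was at 11.11 against 8.12 in replicate 1, with a median of 2.92 over the list. Whole crypts may be the source but cannot be told apart. Stem cell and cell cycle markers had a median difference of -0.128 over 47 genes (SE of the median across genes 0.0471). Genes are not independent replicates and each side is a single array, so this SE does not measure spread between samples. Yet the rise of Lyz1 needs only 6.08% of RNA like that of the stem arrays, which would raise that median by 0.206. Cells that kept Atoh1 cannot be told apart either. Goblet and enteroendocrine markers had a median of 0.0402 over 32 genes (SE of the median across genes 0.0758). Of 22 above background, however, 4 rose by over 1 (log2) and 2 fell by over 1. Among those that rose was Guca2a, picked after its values were seen, from 8.61 to 10.95. A more distal stretch of intestine cannot be told apart as well: 5 distal genes exceeded 7 proximal ones by 0.291 in medians, but the distal genes Fgf15 and Slc10a2 lay below background in every array, and the other 3, Fabp6 (4.90), Cubn (1.35) and Slc51a (-0.18), did not move together.

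Secretory transcripts were also above the background level of 5.64 in the sorted stem cell arrays. Median levels were log2 9.97 for Paneth, 9.71 for goblet and 7.57 for enteroendocrine markers (15 of 19 above background). Levels of different probe sets do not rank the lists by abundance. For the Paneth transcripts, Paneth cells that passed the Lgr5 gate may be a source. Lyz1 was at 14.75 and 15.12, but the 1 alpha-defensin gene measured outside the list, Defa31, reached 6.65, which cannot be told apart from either account because it is a single gene near background. Expression of such genes by the stem cells themselves, or secretory precursors within the gate, was not tested and stays open.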
